A study of Gallus gallus with 205 samples.

How the data were processed

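The labels describe fertilized White Leghorn eggs incubated to Hamburger-Hamilton stage 4, dissection of the primitive streak apart from the rest of the area pellucida, and libraries of single-cell complementary DNA made with a Nextera XT kit. Each library is described as that of 1 cell and is called a cell here. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 0.12.9 (0.12.8 for 1 cell) and RSEM 1.2.3 were used with the genome build galGal4; the notes give no roles or settings, and the annotation and any filter on cells or genes are not given in the sources used here. The deposited values are expected counts per gene, as the authors' RSEM step gives them: 64.4% of the values above 0 are whole numbers and totals differ between cells, so no scaling had been applied. No molecular identifiers are described, so PCR copies are included in the counts.

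There are 2 deposited tables, 1 for the streak and 1 for the surrounding region. The streak table was held here only in part and ended inside a row, which was dropped. All comparisons used the 20581 genes complete in both tables. The surrounding-region table holds 640 more genes with 3.42% of its counts, which were not used here in comparisons and include FGF8, GATA3, FN1 and MKI67; CPM values are relative to the genes used, except those of genes found only in the surrounding-region table, which are relative to all genes of that table. Genes carry the symbols or identifiers of the tables; coordinates were not used, because the tables give none and the gene table at hand is of another build.

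Cells were grouped by the series name in their titles. In cSR, 6 cells carry an epiblast label besides the surrounding-region label (5 as source name and 1 as cell type); they were kept in cSR and left out in an alternative. Library identifiers in the labels fall into 4 consecutive blocks. The cPS and cSR cells share blocks 1 and 2, and cPS1, cPS2 and cPS3 lie in blocks 3 and 4 with no cSR cell, so the main comparison was cPS (27 cells) against cSR (30 cells). No cell was removed. No doublet caller was run; cells with intermediate levels of the W-linked gene HINTW were examined instead. The highest correlation of log2 CPM between 2 cells was 0.857, so no library appeared 2 times.

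Pooled CPM is the sum of a gene's counts over the sum of the cells' totals. Log2 ratios used a pseudocount of 1 CPM, which understates ratios of low genes. A cell counted as detecting a gene at 10 CPM or more. Intervals are exact Poisson intervals of rounded sums and exact Clopper-Pearson intervals of shares, at 95%; 3 counts in the sum of a tissue were taken as the floor. Cells are not replicates, so no p-value or standard error was computed and genes were named by size. A gene passed with a ratio of at least 4-fold, at least 50 CPM and at least 25% of cells in the higher tissue, and at least 2-fold in the same direction in blocks 1 and 2.

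The genes named were set by a rule: the 12 largest ratios each way among named genes past the size rule, up to 4 members of each list with the largest absolute ratio, and a fixed panel. The 21 lists, the cell type markers, the pairs and the alternatives, except those with HINTW, were written before the data were examined. List members under 5 CPM in both tissues were not counted as measured. Random lists drew each member from the 100 genes nearest in mean level, 10000 times. The limit of 25 percentage points for the series, the minimum of 5 cells for pairs counted as measured, the way markers name a cluster, and the limits for HINTW (under 100 CPM low, 700 CPM or more high) were set after the data were examined.

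Cells were clustered with scanpy 1.11.5 and the Leiden method of igraph 0.11.9 on log2(CPM + 1), with 2000 variable genes chosen with the series as batches, values scaled per gene, 15 principal components, 15 neighbours and resolution 1, without batch integration. A cluster was named when at least 3 markers of a class were raised (detected in at least 25% of its cells, with a mean at least 2-fold that of the other cells after adding 10 CPM), more than for any other class, and at least 1 of them was among its 10 leading genes. Not every raised marker is reported here. Scaling alternatives used R 4.3.3 on the cPS and cSR cells. They were TMM factors of edgeR 4.0.16, which shifted log2 ratios by 0.054, and size factors of DESeq2 1.42.0. The latter were taken over the 2075 genes found in every cell of these 2 series. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and plots used matplotlib 3.10.9. Counts were also thinned to 1000000 per cell, which left out 1 cell of cPS2, 2 of cPS3 and 2 of cSR.

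The comparison was tested on simulated data for the same 20581 genes, drawn with the real means, dispersions and totals, with 200 genes changed between cPS and cSR. Each gene was drawn independently, so the simulated cells hold no genes that vary together. Of genes changed 4-fold, the threshold itself, 41.8% passed the rule; of those changed 8-fold 92.5% passed and of those changed 16-fold 98.5%. In 20 draws with no change, a median of 21 genes passed (14 to 26) and a median of 2 lists, at most 5, lay outside the central range. One gene, LOC101748795, took 2.60% of all counts, with medians per cell of 3.65%, 3.81%, 1.36% and 2.18% in blocks 1 to 4.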

Results

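Transcripts were counted in 205 single cells of White Leghorn chicken embryos at Hamburger-Hamilton stage 4, when the primitive streak, the midline groove through which epiblast cells ingress to form mesoderm and endoderm, runs along most of the area pellucida. The streak had been dissected out of the embryos, and the remaining area pellucida was collected as the surrounding region. The streak gave 175 cells in 4 title series, called cPS (27 cells), cPS1 (37 cells), cPS2 (59 cells) and cPS3 (52 cells), and the surrounding region gave 30 cells in the series cSR. The labels do not say what the series numbers stand for and name no embryo, so each tissue is 1 sample, and no difference below has a replicate check. The total of expected counts per cell had a median of 2459318 and ranged from 201170 to 4552697, and a cell had a median of 4784 genes at 10 counts in 1000000 (CPM) or more, with a range of 3948 to 6336. Median totals were close in the 2 series that were compared, at 2485547 in cPS and 2478990 in cSR. Intervals are 95% intervals that cover counting error only (exact Poisson for pooled CPM, exact binomial for shares of cells), and counts made without molecular identifiers are not independent molecules.

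Cells of the streak were set against cells of the surrounding region to ask which transcripts differ between the 2 tissues. The transcript of CHRD, the secreted BMP antagonist of the node and anterior streak, had the largest ratio: it stood at 54.6 CPM (52.9 to 56.3) in cPS and 0.229 CPM (0.131 to 0.371) in cSR, a log2 ratio of 5.50, and was detected in 33.3% of cPS cells (16.5 to 53.96) and in 0 of 30 cSR cells (upper bound 11.6%). The chemokine receptor CXCR4 was also higher in the streak, at 439 against 33.7 CPM, as was TRABD2B, a metalloprotease that acts on WNT ligands, at 712 against 65.9 CPM, each in 55.6% of cPS and 26.7% of cSR cells. A single cell gave 39.4% of the cPS counts of CXCR4 and 40.5% of those of TRABD2B, and a single cell 46.8% of the cSR counts of CXCR4; without each gene's highest cell per tissue the log2 ratios were 3.83 and 3.23. With cPS3 in place of cPS that of CXCR4 was 0.96. Highest above the streak in the surrounding region was AMN1, at 183 CPM (180 to 186) against 3.48 CPM (3.06 to 3.93), a log2 ratio of -5.36, detected in 66.7% of cSR cells (47.2 to 82.7) and 7.41% of cPS cells (0.910 to 24.3). The heparin-binding growth factor PTN followed the same direction, at 131.1 against 11.7 CPM, and so did the caudal-type homeobox gene CDX4, at 151.3 against 36.8 CPM.

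In all, 60 genes passed a fixed rule of size, which asked for a ratio of at least 4-fold, at least 50 CPM and 25% of cells in the higher tissue, and a ratio of at least 2-fold in the same direction in both blocks of library identifiers that hold cells of both series. Of these, 22 were higher in the streak, with a median log2 ratio of 2.69, and 38 were higher in the surrounding region, with a median of -2.49. The others with a gene name among the 12 largest ratios towards the streak were NSUN6 (log2 ratio 4.43), APOA1 (4.27), SERTM1 (2.75), KCNG1 (2.496), LBH (2.49), PDE3B (2.44), PIK3R5 (2.42), MYL4 (2.21) and RIPK1 (2.09). APOA1, an apolipoprotein of endoderm and yolk-associated tissue, reached 282 CPM in cPS against 13.6 CPM in cSR, but a single cell gave 68.7% of its cPS counts. It was detected in 25.9% of cPS and 33.3% of cSR cells, and its log2 ratio was 0.02 in cPS3. Towards the surrounding region the others were GUCA1C (-3.49), ZC3H12A (-3.40), NPBWR1 (-3.27), FAM169A (-3.09), GREB1L (-3.05), DENND6A (-2.97), CPLX2 (-2.88), TRIM37 (-2.78), KLHL5 (-2.74) and RASGRP1 (-2.73). RIPK1 turned to -0.17 among cells with even title numbers and GUCA1C to 0.066 among cells with low levels of HINTW, a W-linked gene of female birds. For 7 genes of the first set and 3 of the second the tables gave an identifier in place of a gene name.

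The other 3 streak series were set against the same cSR cells. The direction was the same in all 3 for 51 of the 60 genes (85%), and the ratio was at least 2-fold in all 3 for 28 (46.7%). Because the cSR cells were shared, cells simulated without any difference gave 91.8% and 35.3% for these shares. The genes at least 4-fold in all 3, singled out after their values were seen, were CHRD, NSUN6, TRABD2B and the unnamed LOC101747643 towards the streak, and AMN1, NDRG1, CDH6 and FBN2 towards the surrounding region. TRIM37, by contrast, had log2 ratios of 0.04, 0.01 and -0.01 in cPS1, cPS2 and cPS3. A single cell gave 54.4% of the cSR counts of NDRG1 and a single cell 61.5% of its cPS counts. CDH6 was detected in 1 cPS cell, and a single cell gave 96.2% of its cPS counts. In cPS against cSR, log2 ratios in blocks 1 and 2 were -1.01 and -4.96 for NDRG1 and -1.27 and -5.71 for CDH6.

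Simulated unchanged cells gave a median of 21 genes past the rule, with a range of 14 to 26 over 20 draws, so membership of a single gene among the 60 carries that uncertainty. Genes were simulated independently of each other, whereas real genes can vary together in the same few cells, so this range can be too narrow. The count was 23 with all 175 streak cells, 12 of them among the 60, and without the 6 cSR cells whose labels also say epiblast it rose from 0.292% to 0.496% of the 20581 genes compared. The share of genes higher in the streak was 36.7%, but 48% with DESeq2 size factors, 53.3% at an 8-fold limit and 54.35% with cPS1 in place of cPS.

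**Figure D1:**
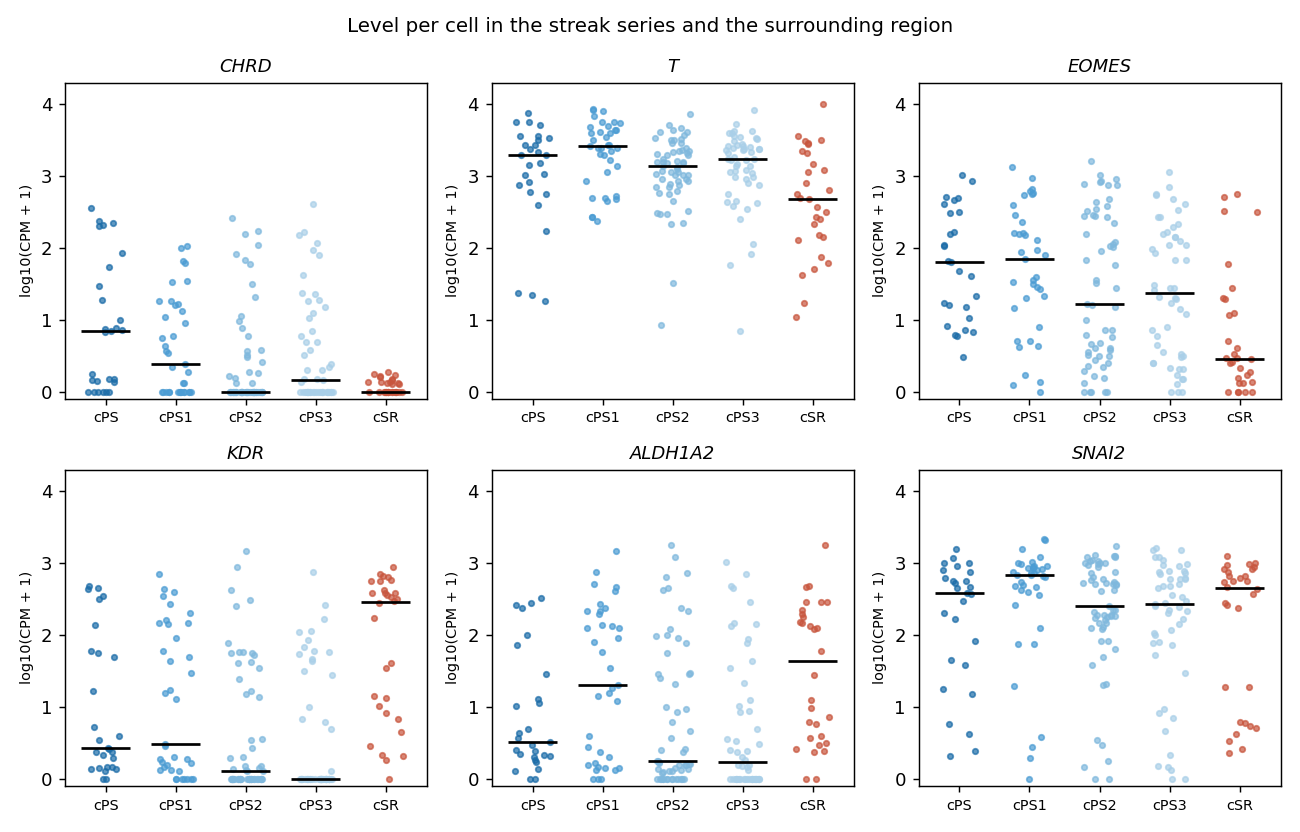
Level of 6 genes in each cell, as log10(CPM + 1) on the vertical axis, in the 4 streak series and in the surrounding region (cSR); each point is 1 cell and the black line is the median of the series. CHRD reached 10 CPM in none of the 30 cSR cells, T was present in nearly every cell of both tissues, and KDR had a higher median in cSR than in each streak series.

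Gene lists fixed before the data were examined were compared between the same cPS and cSR cells, to ask which programmes of gastrulation differ between the tissues. Each list was described by the median log2 ratio of its measured members and the percentile of that median among 10000 random lists matched on expression. Of 21 lists, 8 lay outside the central 95% of random lists, against a median of 2 and a maximum of 5 in simulated unchanged cells, and several lists share members. Genes were simulated independently of each other, and random lists draw unrelated genes. Neither holds members that vary together in the same few cells, so both can understate how many lists lie outside without a difference between the tissues. The anterior streak and node list had a median of 1.78 (percentile 100), with 4 of 7 measured members at least 2-fold higher in the streak and 0 lower. Besides CHRD these were the pioneer factor FOXA2 (8.51 against 0.0714 CPM, in 8 cells of cPS and 0 of cSR), the node homeobox gene GNOT1 (25.1 against 3.49 CPM) and the secreted antagonist CER1 (104.7 against 29.8 CPM). OTX2 stood at 8.98 against 18.7 CPM, with log2 ratios of -1.96 in identifier block 1 and 1.54 in block 2. The list's median was 1.51 in block 1 and 1.54 in block 2, and 0.07 (percentile 71.9) when members of any level were counted. It was 0.73 (percentile 93.6) with cPS2 in place of cPS and 0.36 (percentile 70.6) among cells with high levels of the W-linked gene HINTW, within the central range in both.

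The pan-streak mesendoderm list had a median of 0.47 (percentile 99.9), with 2 of 8 members at least 2-fold higher and 0 lower, and block medians of 0.63 and 0.32 (percentile 89.1 in block 2). The list also lay within the central range with cPS2 in place of cPS (percentile 97.47), with even title numbers (81.9) and among cells with low HINTW (93.2). EOMES, a T-box factor of mesendoderm, stood at 186 CPM (182 to 189) in cPS and 46.2 CPM (44.6 to 47.8) in cSR. MSGN1, a factor of paraxial mesoderm, stood at 93.6 against 38.6 CPM. T, the Brachyury gene that marks the streak, was less than 2-fold apart by pooled CPM. It stood at 2218 CPM (2207 to 2229) in cPS and 1194 CPM (1186 to 1202) in cSR. The medians of T per cell were further apart, at 1944 CPM in cPS and 486 CPM in cSR, where the highest cell reached 10010 CPM. T was detected in 29 of the 30 cSR cells. SNAI2, a driver of the epithelial-mesenchymal transition, was at 440 CPM (435 to 445) in cPS and 432 CPM (427 to 437) in cSR.

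The endoderm and hypoblast list had a median of 2.46 (percentile 100), with 6 of 8 members at least 2-fold higher in the streak and 0 lower. They were APOA1, CXCR4, FOXA2, CER1, the retinol carrier RBP4 (70.1 against 6.80 CPM) and HHEX (30.5 against 11.3 CPM). A single cell gave 78.7% of the cPS counts of RBP4 and a single cell gave 57.9% of those of HHEX. The log2 ratio of RBP4 was -3.11 in block 2, -0.91 with cPS3 in place of cPS and -1.305 among cells with low HINTW. The list's median was 3.12 in block 1 and -0.18 in block 2 (percentile 44.04), and -0.002 when members of any level were counted (percentile 70.3). With cPS3 in place of cPS it was 0.02 (percentile 47.8).

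Mesoderm genes were lower in the streak than in the surrounding region, with a list median of -1.18 (percentile 0.010) and 6 of 12 members at least 2-fold lower. FOXF1, a forkhead factor of lateral mesoderm, stood at 3.67 against 18.4 CPM, and the haematopoietic factor LMO2 at 2.18 against 24.0 CPM. MSGN1 and MESP2 were the 2 members at least 2-fold higher. KDR, the VEGF receptor of vascular progenitors, stood at 81.7 CPM (79.6 to 83.8) in cPS and 289 CPM (285 to 293) in cSR, and ALDH1A2, the enzyme that makes retinoic acid, at 52.8 against 195 CPM; these 2 genes were singled out after their values were seen. The list's median was -0.01 in block 1 (percentile 54.8) and -2.42 in block 2, and ALDH1A2 had log2 ratios of -0.08 and -3.67 in these blocks, and LMO2 0.26 and -2.94. By mean CPM per cell, KDR was also closer between the tissues in block 1 than in block 2. The list also lay within the central range with odd title numbers (percentile 15.6), among cells with high HINTW (7.645) and with members at 20 CPM or more (5.215).

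The posterior streak list (median -0.57, percentile 1.17) and the list of BMP targets and ligands (median -0.53, percentile 1.45) were also lower in the streak. In the first, 4 of 12 members were at least 2-fold lower, namely FOXF1, CDX4, MSX2 (3.25 against 13.2 CPM) and GATA2 (75.9 against 155.3 CPM), and MSGN1 was higher. The log2 ratio of GATA2 was 0.34 with cPS1 and 0.024 with cPS2 in place of cPS. In the second, 3 of 12 members were at least 2-fold lower: MSX2, the inhibitory SMAD gene SMAD6 (24.0 against 85.6 CPM) and ID2, an immediate BMP target (807 against 1682 CPM). CHRD was its single member at least 2-fold higher. Block medians were -0.26 and -1.001 for the posterior streak list and -0.03 and -1.18 for the BMP list, and in block 1 both lay within the central range (percentiles 22.5 and 44.7). With cPS1 and cPS2 in place of cPS both lists also lay within it, the posterior streak list at medians of 0.14 and -0.045 and the BMP list at percentiles 8.80 and 14.1. With cPS3 the BMP list was at percentile 6.735, and with all streak cells the posterior streak list was at percentile 9.54. Over 21 alternatives the posterior streak list kept its call in 14 and the BMP list in 13.

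The dissociation stress list moved with these groups, with a median of -0.62 (percentile 0.085). JUN stood at 59.1 against 130 CPM and ATF3 at 41.9 against 83.9 CPM, whereas HSPA2 was higher in the streak at 358 against 138.3 CPM. The list's median was -0.46 in block 1 and -0.24 in block 2, within the central range in both, and 0.008 with all streak cells (percentile 50.4). The blood and extraembryonic list had a median of -2.97 (percentile 0.015) over 5 measured members, and the single highest cSR cell of each gene gave 82.3% of the counts of CDH5 and 65.5% of those of LMO2 in that tissue. Its median was 0.59 in block 1, where 2 members were measured, and -2.94 in block 2. Without each gene's highest cell per tissue it was -1.59 (percentile 5.71), and with members of any level -0.051 (percentile 4.95), within the central range in both. The germ cell list, with 3 measured members, had a median of -0.83 (percentile 8.48).

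The remaining 12 lists lay within the central range in cPS against cSR. Nodal pathway genes had a median of 0.39 (percentile 96.7), with LEFTY2 at 78.3 against 23.1 CPM (a single cell gave 91.3% of its cSR counts) and SMAD2 at 59.4 against 151.01 CPM (log2 ratios of 0.060 with cPS1 and 0.16 with cPS2), and the hox and cdx list had a median of -0.70 (percentile 3.41), with HOXB5 at 12.5 against 44.1 CPM. The nodal list lay above the central range with all streak cells (percentile 99.65) and with cPS1, cPS2 and cPS3 (percentiles 99.7, 99.3 and 99.02). Epithelial junction genes had a median of 0.30 (percentile 95.3) and 0 of 7 members past 2-fold, with CLDN1 at 2110 against 1208 CPM; with all streak cells the percentile was 99.99. Genes of the epithelial-mesenchymal transition and the extracellular matrix had a median of -0.10 (percentile 39.8) with members both ways: VIM was at 233 against 78.4 CPM and the basement membrane collagen COL4A1 at 15.4 against 43.004 CPM. FGF targets and ligands had a median of 0.20 (percentile 82.4), WNT targets and ligands -0.16 (percentile 32.5), notch pathway genes -0.20 (percentile 27.6), epiblast and neural plate genes -0.17 (percentile 20.0), and non-neural ectoderm and border genes 0.13 (percentile 72.2). Among the notch ligands JAG2 stood at 0.488 against 16.2 CPM, but its log2 ratio was 0.15 with cPS1 in place of cPS. The G2 and M phase list had a median of -0.25 (percentile 6.67), and the S phase list had a median of -0.01 (percentile 67.9) but a mean of 0.06. With all streak cells the S phase list was at percentile 99.2 and the glycolysis list at 0.940. Glycolysis genes had a median of 0.20 (percentile 87.7), with the glucose transporter SLC2A3 at 853 against 319 CPM.

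**Figure D2:**
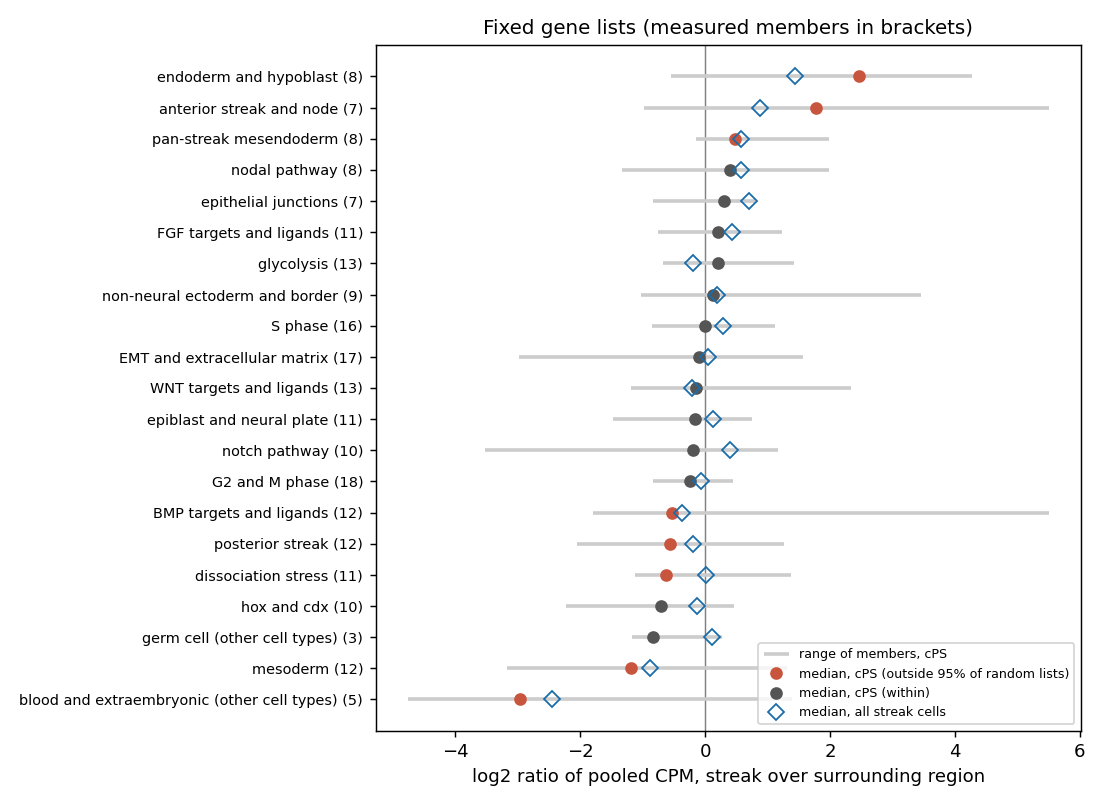
Median log2 ratio of streak over surrounding region for each of the 21 fixed lists (circles, cPS against cSR; red where the median lies outside the central range of random lists), with the range over measured members as a grey bar and the median with all streak cells as an open diamond. The endoderm and hypoblast list is highest at 2.46 and the blood and extraembryonic list lowest at -2.97, and the dissociation stress list moves from -0.62 to 0.008 with all streak cells.

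The 4 streak series were described with a fixed panel of 28 genes to ask how far the streak samples resemble each other. T was detected in 173 of 175 streak cells (98.9%, 95.9 to 99.9), CDH2 in 87.4%, SNAI2 in 86.3% and the paraxial mesoderm gene TBX6 in 85.7%. Node and anterior streak genes were found in fewer cells: CHRD in 25.1% (18.9 to 32.3), LHX1 in 20.0%, FOXA2 in 12.6% and the organizer gene GSC in 8.57%. The neural gene SOX2 was detected in 2.29% and the epithelial cadherin CDH1 in 5.14% of streak cells, whereas SOX3 was detected in 26.3% and NANOG in 52.6%. MIXL1, SOX17 and HAND1 reached 10 CPM in 0 of 175 cells, which allows a share of up to 2.09%.

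GATA2 had the widest range of detection between the series, from 51.9% of cPS cells (31.95 to 71.3) and 75.9 CPM to 89.2% of cPS1 cells (74.6 to 96.97) and 197 CPM. MSGN1 ranged from 22.0% of cPS2 cells (12.3 to 34.7) to 48.6% of cPS1 cells (31.9 to 65.6). These were the only panel genes with a range of at least 25 percentage points, a limit set after the values were seen, and LHX1 came next with 24.3 points. The cPS cells lie in identifier blocks 1 and 2 and the other 3 series in blocks 3 and 4, so for cPS against the others series and block cannot be told apart. Only cPS2 has cells in both blocks 3 and 4, where GATA2 was detected in 70.97% and 67.9% of its cells and MSGN1 in 19.4% and 25%. All cPS1 cells lie in block 3, so the difference in MSGN1 detection between cPS1 and cPS2 was also present within that block. Pooled levels there were 70.7 CPM in cPS1 and 57.4 CPM in cPS2, and cPS, at 93.6 CPM, was above both. In block 3, 14 of 37 cPS1 cells and 6 of 31 cPS2 cells lay in a cluster with more detected genes, described below. Intermediate levels of HINTW were found in 24.3% of cPS1 and 3.39% of cPS2 cells. Whether this bears on detection was not tested.

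**Figure D3:**
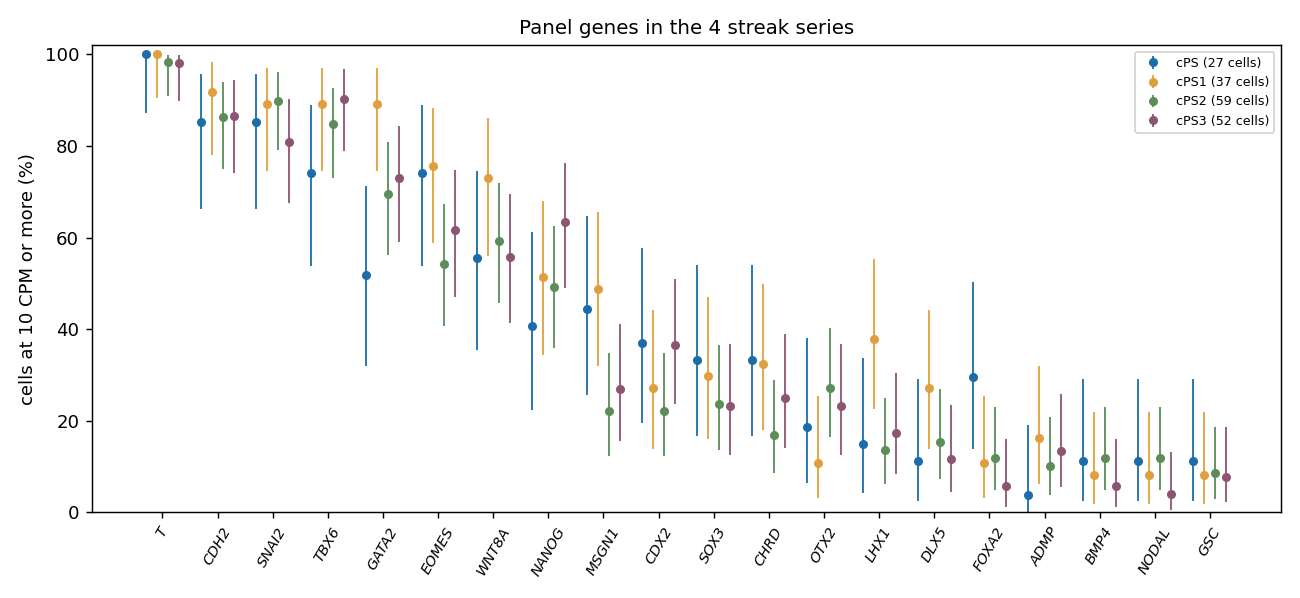
Percent of cells at 10 CPM or more (vertical axis) for the 20 panel genes detected in at least 10 streak cells, in the 4 streak series; points are shares and bars are exact 95% binomial intervals over cells. T is near the top in all 4 series, and GATA2 spans 51.9% in cPS to 89.2% in cPS1.

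Pairs of genes fixed in advance were examined for joint detection in the 175 streak cells, to ask whether markers of different streak regions occur in the same cell. GSC and CHRD, both genes of the organizer, were detected together in 11 cells (6.29%, 3.18 to 10.97), where independence within each series would give 3.82, and the observed number was above the expected number in 3 of the 4 series. GSC and WNT8A, a ligand of the more posterior streak, were detected together in 4 cells against 9.05 expected, and in none of the series was the observed number above the expected number. T was found with SOX3 in 46 cells against 45.5 expected, but T was detected in 173 of the 175 cells, so this number could hardly depart from the expected one. CHRD was found with TBX6 in 35 cells against 37.6 expected. BMP4 and CHRD shared 3 cells against 3.91 expected. CDH1 was found with CDH2 in 8 cells, against 7.945 expected, and with SNAI2 in 8 cells, against 7.88 expected. GSC with WNT8A was found in 7 cells against 11.2 expected with thinned counts. Without cells of intermediate HINTW it was found in 3 cells against 7.46 expected. Both settings reuse the same cells and are not independent of the main result. At 50 CPM it was found in 0 cells against 1.6 expected, a number too small to show a shortfall. At a level of at least 1 count no shortfall was seen, with 43 cells against 42.55 expected. GSC with CHRD was found in 37 cells against 28.7 expected at 1 count and in 2 cells against 0.612 expected at 50 CPM. Without cells of intermediate HINTW it was found in 9 cells against 3.07 expected. A library that held more than 1 cell, a candidate raised below, would also give joint detection.

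Clustering of all 205 cells by expression gave 8 clusters, which were named from fixed markers where at least 3 were raised. A node and anterior streak-like cluster of 24 cells (raised markers GSC, CHRD, LHX1 and FST) and an endoderm or hypoblast-like cluster of 11 cells (HHEX, APOA1, RBP4 and CER1 among those raised) held streak cells only. For each of them, 0 of 30 cSR cells allows a share of up to 11.6%. A mesoderm-like cluster (FOXF1, KDR, LMO2 and ALDH1A2) held 28 cells, 16 of the streak and 12 of the surrounding region. Of the 175 streak cells, 13.7% (8.99 to 19.7) were in the node and anterior streak-like cluster, 9.14% (5.32 to 14.4) in the mesoderm-like cluster and 6.29% (3.18 to 10.97) in the endoderm or hypoblast-like cluster. These intervals do not cover the choice of settings: the mesoderm-like share was 33.7% at resolution 0.5 and 14.9% with 10 principal components. The endoderm or hypoblast-like share was 11.1% of cPS cells (2.35 to 29.2) and 1.92% of cPS3 cells (0.0487 to 10.3). The other 5 clusters, with 70.9% of the streak cells, stayed unnamed, among them a cluster of 33 cells whose leading genes included MSGN1, DLL1 and LEFTY2. Shares are not compared between tissues, since genes that define the clusters differ between them. The assignment of cells moved with the settings, with an adjusted Rand index of 0.451 to 0.823 against the clusters described, and the node and anterior streak-like name was given in only 1 of the 9 alternatives. The endoderm or hypoblast-like name was lost in 4 of them, and no cluster was named when blocks 1 and 2 were clustered apart.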

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

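The tests of T in the surrounding region, and the test of genes past the size rule that splits the cSR cells, were chosen after the results were seen. The test on female and male cells was fixed before its result was seen.

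T, the Brachyury gene that marks the streak, had a median of 486 CPM per cell in cSR and 1944 CPM in cPS, and 24 of the 30 cSR cells had at least 100 CPM. If reads of streak libraries had been assigned to cSR libraries, CHRD would be carried over at about the ratio of T, but the ratio of cSR to cPS was 53.8% for T and 0.419% for CHRD, with an upper bound of 0.702%. Cells carried over from along the whole streak would bring node and anterior streak markers. Cells from parts of the streak without such markers would not. Of all streak cells, CHRD was detected in 25.1% and FOXA2 in 12.6%. For CHRD and FOXA2, 2 of 8 such markers, the cSR share had an upper bound (11.6%) below the lower bound in cPS (16.5% and 13.75%). The other markers could not meet this criterion. Even 0 of 30 cSR cells gives an upper bound of 11.6%, and their lower bounds in cPS were at most 11.1%. LHX1 was detected in 13.3% of cSR and 14.8% of cPS cells and FST in 33.3% and 25.9%, and GSC and ADMP each in 1 cSR cell. The number of cells limits this test to CHRD and FOXA2, and streak cells carried over cannot be told apart from T transcripts of the surrounding region itself.

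A different mixture of female and male embryos in the tissues was examined for the 60 genes past the size rule. Of them, 55 kept a 2-fold difference in the same direction both among cells with high HINTW, a W-linked gene of female birds, and among cells with low HINTW. The genes had been chosen for size in these same cells, and 57 kept it with odd title numbers and 58 with even ones. A split by HINTW could therefore hardly come out otherwise, and no conclusion on the mixture is drawn from it. To ask whether such genes belong to the cPS series alone, genes were chosen with odd or even cSR cells and looked up in the other series against the remaining cSR cells. Of these 177 genes, each counted 1 time, 46.9% (39.4 to 54.5) had the same direction in cPS1, cPS2 and cPS3, where unchanged simulated cells gave 31.7%. Apart, the share was 58.6% for genes chosen with odd cSR cells and 47.0% with even ones. A ratio of at least 2-fold in all 3 series was seen for 14.7% of the 177 genes, where unchanged simulated cells gave 4.65%. The share with the same direction lies above the simulated one and below the bound set for a difference of the whole streak, so tissue and series cannot be told apart for these genes. They are a wider set than the 60 genes, and only 25 of them passed with both the odd and the even cSR cells. The share therefore does not bear directly on the 60 genes. A difference between the tissues stays open and untested, since each is 1 sample.

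The surrounding-region table holds fixed-list genes whose streak values were not analysed here, and 13 of them had more counts than the limit of 3 that a count of 0 allows; their CPM values are relative to all genes of that table. FN1, the matrix protein fibronectin, stood at 112.9 CPM and was detected in 28 of 30 cells. FGFR2 stood at 67.03 CPM, and the proliferation gene MKI67 and the glycolysis gene PGAM1 at 338 and 514 CPM. The secreted WNT antagonist FRZB stood at 37.99 CPM and the integrin gene ITGA6 at 22.4 CPM. WNT5B stood at 8.54 CPM, GATA3 at 7.44 CPM, FZD7 at 5.001 CPM and FGF8 at 1.34 CPM, the last detected in 2 of 30 cells. HOXD3 (0.248 CPM), SFRP5 (0.110 CPM) and HOXD4 (0.0828 CPM) were near the floor.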

How the results depend on the processing

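The alternatives with high, low or intermediate HINTW were chosen after seeing the data; the others were fixed before. No paired analysis was possible because the title numbers only name cells, and no result comes from a test with a p-value. Of 93 named genes over 19 alternatives, 1462 values stayed on their side of 2-fold, 184 fell below it, 85 passed it in either direction and 36 that had been at least 2-fold changed sign; of list medians, 367 kept their call, 37 lost it, 31 gained a call and 6 that had been outside the central range changed sign. Genes under 2-fold and lists within the central range also changed sign in some settings and are not in these counts of sign changes. The 60 genes (22 higher in the streak and 38 higher in the surrounding region) were within 1.5 times that number with mean CPM (49), TMM (63), DESeq2 size factors (50), each gene's highest cells left out (66), no intermediate HINTW (63) and no condition on blocks (69). Shares of rare genes rest on few cells, and a gene at 0 of 30 cSR cells can have a share of up to 11.6%.

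Counts of genes past the size rule are given here as percent of the 20581 genes compared, where the 60 genes are 0.292% (0.107% higher in the streak and 0.185% higher in the surrounding region); pairs in parentheses keep that order. Changes of threshold moved the share by construction. A pseudocount of 10 CPM gave 0.136% (0.0632 and 0.0729), no filter 2.599% (1.001 and 1.599), a 2-fold limit 0.914% (0.3498 and 0.564) and an 8-fold limit 0.0729% (0.0389 and 0.0340). Fewer cells make pooled values noisier, and the settings with 1 block or 1 HINTW class have no condition on blocks. Block 1 only gave 0.996% (0.413 and 0.583), block 2 only 1.297% (0.549 and 0.748), odd title numbers 0.641% (0.277 and 0.364), even title numbers 1.011% (0.306 and 0.7045), high HINTW 0.909% (0.364 and 0.544) and low HINTW 1.56% (0.646 and 0.914). For the next values the cause was not tested. All streak cells gave 0.112% (0.0389 and 0.0729) and cSR without the cells labelled epiblast 0.496% (0.199 and 0.296). Higher in the surrounding region were 0.102% with cPS1 in place of cPS, and higher in the streak 0.0680% with cPS2.

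The number of lists outside the central range, 8 with cPS, was 4 with odd title numbers and 5 with low HINTW. It counts any list outside in that setting, not only the 8, and the cause was not tested. Panel genes with a range of 25 points rose from 2 to 7 at 1 count, and pairs with at least 5 cells from 7 to 13 at 1 count and to 2 at 50 CPM, as the threshold sets. The mesoderm share of streak cells, 9.14%, was 33.7% at resolution 0.5, 14.9% with 10 principal components and 18.9% with blocks 3 and 4 apart; the cause was not tested.

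The following log2 ratios, of genes at least 2-fold apart and lists outside the central range with cPS, changed sign, and the cause was not tested. With all streak cells JAG1 was 0.62 and MEIS1 0.72. With cPS1 GATA2 was 0.34, JAG1 1.175, JAG2 0.15, MEIS1 0.52, SMAD2 0.060 and TRIM37 0.043. With cPS2 COL4A2 was 0.050, GATA2 0.024, JAG1 0.59, MEIS1 0.34, SMAD2 0.16, TCF7 0.19 and TRIM37 0.0087. With cPS3 JAG1 was 0.81, MEIS1 1.67 and RBP4 -0.91. In block 1 CDH5 was 0.96, CDT1 -0.40 and LMO2 0.26, and in block 2 FGF19 -0.38, HESX1 0.098, RBP4 -3.11, SFRP2 0.045 and TCF7 0.83. With odd title numbers CDH5 was 0.37, HESX1 0.18 and LMO2 0.10, and with even ones CDT1 -0.335, DUSP1 0.86 and RIPK1 -0.17. With high HINTW DUSP1 was 0.14, and with low HINTW GUCA1C was 0.066, RBP4 -1.305 and SOX3 2.06. Of list medians, dissociation stress was 0.0084 with all streak cells, posterior streak 0.14 with cPS1, blood and extraembryonic 0.59 in block 1 and 0.39 with odd title numbers, and endoderm and hypoblast -0.18 in block 2 and -0.0021 with members of any level.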

Other observations

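The test of library totals was chosen after its first result was seen, and the test of HINTW in the cluster was fixed before its result was seen.

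HINTW, a gene of the female-specific W chromosome, was divided into 3 classes by limits set after the data were examined: 62 cells were high (median 1254 CPM), 17 intermediate (227 CPM) and the rest low (1.64 CPM). SPINW, another W-linked gene, was detected in 74.2%, 35.3% and 1.59% of these cells. High cells made up 48.1% of cPS (28.7 to 68.1), 15.3% of cPS2 (7.22 to 26.99) and 63.3% of cSR (43.9 to 80.1). Intermediate cells had a median of 5593 genes at 10 CPM or more, against 4773 in low and 4703 in high cells.

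A cluster of 32 streak cells, all in identifier blocks 3 and 4, had a median of 5766 genes against 4676 in the other streak cells of these blocks, with a lower median total (1653831 against 2662553) and a higher mean level of T (3706 against 1783 CPM). Lower totals alone are argued against: although 72.7% (49.8 to 89.3) of the 22 cells with totals under the cluster's median belong to it, cells thinned to 1000000 counts still had a median of 5824 genes in the cluster (lower quartile 5514) and 4711 in the others (upper quartile 4930). Intermediate HINTW was found in 12 of the 32 cells (37.5%, 21.1 to 56.3) and in 3 of the others (2.59%, 0.537 to 7.37). A candidate explanation is that some of these libraries hold 2 or more cells, of a female and a male embryo where HINTW is intermediate. The CPM of such a library lies between those of its cells, so mixing alone would not raise the mean level of T. No biological explanation was tested.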
